A study of Mus musculus with 13 samples.

How the data were processed

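Cortical RNA of 13 male mice was profiled by RNA sequencing, 7 labelled KO and 6 labelled WT. Groups were taken from the genotype label of each sample. Per the labels' protocols, RNA was purified from frozen tissue, libraries were made with a stranded poly(A) mRNA kit and sequenced on a HiSeq instrument. The molecule field of the same labels reads total RNA. STAR and the mouse build mm10 are named in the submitters' processing notes, without versions. The remaining steps between the reads and the tables are not given in the sources used here.

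The authors deposited a gene table of natural log expression values for each library and a table of their own KO against WT comparison. Both are tables of MMDIFF, a Bayesian model that compares expression estimates which share reads between similar transcripts. The natural log values deposited by the authors carry the name of log TPM in the companion table, but after exponentiation they sum to between 576350 and 1526371 per library, so they were used here as relative levels only. Each library has 1 floor value, between -9.61 and -9.14 on the log2 scale, for genes without support, and between 1506 and 2132 of the 20996 genes stood at it. The authors' comparison table gives per gene a Bayes factor, which is a ratio of evidence, a posterior probability, which is a fraction between 0 and 1, and an effect on the natural log scale. It also gives counts of unique reads per gene and library as the authors deposited them. At least 93.1% of these counts were even in every library, as when both ends of a pair are counted, and they are low for genes whose transcripts resemble others, so they are not whole read counts. Group means and SDs on the natural log scale in the authors' deposited table did not match the values per library and were not used in any test.

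Natural log values were divided by the natural log of 2 and tested without pseudocount or further scaling with limma 3.58.1 in R 4.3.3 (linear model with moderated variances, trended and robust, statmod 1.5.0, two-sided). Adjusted p-values are Benjamini-Hochberg values over the genes tested, called at 0.05. The planned filter was a mean level of at least 1 unit, with a fallback if the unit gave that number no fixed meaning. Since the levels have no common total, the fallback was used, before any calls were compared: genes above the 40th percentile of the mean level over the 13 libraries, which lies at 0.189. This left 12597 genes, of which 12127 carry a gene ID of the GENCODE M21 annotation of GRCm38, the assembly also known as mm10. Coordinates are from that annotation. Fold changes are ratios of geometric means. Levels are linear means ± SD in the deposited units.

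Before the data were examined, 45 gene lists were fixed, 27 for responses to failing mitochondrial translation and neuronal damage and 18 of cell type markers. Of these, 42 had at least 3 tested members. Choroid plexus markers and markers of T, B and NK cells each had 2 tested members, and none of the peripheral myeloid markers was tested. Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 42 lists, and again with the correlation estimated from the data. Each list also has a score per library, the mean log2 level of its members relative to the WT mean, tested by an exact two-sided permutation over all 1716 splits of the libraries. The genes named are Dars2, the 8 largest rises and 8 largest falls among called genes with a mean level of at least 1 in the higher group and a gene symbol that is not a clone name, and up to 4 called members of each list with the largest change. Other members are given as values and were chosen after their values were seen: Asns, Shmt2, Hmgcr, mt-Nd2, B2m, Hexb, Slc17a7, Fos, Gad1 and Cldn5. The spread of each list's scores within KO was set against that within WT by an exact permutation of the labels. Its statistic was the difference between groups in mean absolute deviation from the group median.

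The alternatives tried were no filter, filters at mean levels of 5 and 1, pseudocounts of 0.1 and 1, median centring, quantile normalization, moderation without trend and robust options, sample quality weights, an exact Wilcoxon test, a block for the replicate number, each library left out in turn, the rotation test fry, the authors' own estimates, the 18S rRNA level as a covariate, and the edgeR 4.0.16 quasi-likelihood test on the unique reads with TMM scaling. The level filter of 1, the 18S covariate, edgeR and the permutation of list scores were added after seeing the data. In simulated data with the pooled SD of each of 12597 genes, limma recovered 34.0% of genes changed by 0.5 on the log2 scale, 76.0% at 1, 90.0% at 2 and 100% at 3. Of its 159 calls, 9 (5.66%) were false, and no gene was called when none was changed. The simulated genes were independent and had the same SD in both groups, unlike the real libraries. These rates therefore need not hold for the real data. No pair of libraries had identical values, and the smallest chi-square per degree of freedom of unique reads between a pair was 4.04, so each library was counted as 1 replicate. Unique reads are not independent molecules, so limits set by few reads cover counting error only. Figures were drawn with matplotlib 3.10.9.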

Results

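The cortex of male mice with floxed alleles of Dars2 was compared between animals with and without Cre recombinase under a CamKII promoter, which is active mainly in excitatory neurons of the forebrain. Dars2 encodes the mitochondrial aspartyl-tRNA synthetase, which charges the aspartate tRNA used for protein synthesis inside mitochondria. The 7 libraries with Cre are called KO and the 6 without are called WT. The sample labels give an age of 14 weeks and the series description gives 5 weeks, so the age is uncertain. The series description counts 7 and 6 mice, which makes each library 1 animal. Unique reads per library ranged from 5107753 to 7369914, with a mean of 6384000 ± 908000 (SD, n = 7) in KO and 6608000 ± 517000 (SD, n = 6) in WT. The mitochondrial rRNA mt-Rnr2 took between 29.9% and 41.3% of these reads.

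The targeted gene was measured first. Dars2 (ENSMUSG00000026709, a protein-coding gene on the minus strand of chromosome 1, 161040601 to 161070658 in GRCm38) had a level of 0.444 ± 0.040 (SD, n = 7) in KO and 0.477 ± 0.122 (SD, n = 6) in WT. KO levels by replicate number were 0.443, 0.408, 0.442, 0.528, 0.447, 0.429 and 0.413, and WT levels were 0.553, 0.477, 0.436, 0.664, 0.305 and 0.428. The log2 fold change was -0.07 with a standard error of 0.155 and a 95% interval from -0.40 to 0.26, which allows a fall of up to 24.2%. Its exact permutation p was 0.666 (limma adjusted p = 0.858), and the difference was smaller than the spread between replicates. The sign turned without WT replicate 4 (0.0354) and with edgeR on unique reads (0.264), of which each library had between 4 and 18. Values are for the whole gene, the deleted part is not given in the sources used here, and cells without Cre keep the gene. Dars2 therefore did not check the genotype labels.

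**Figure D1:**
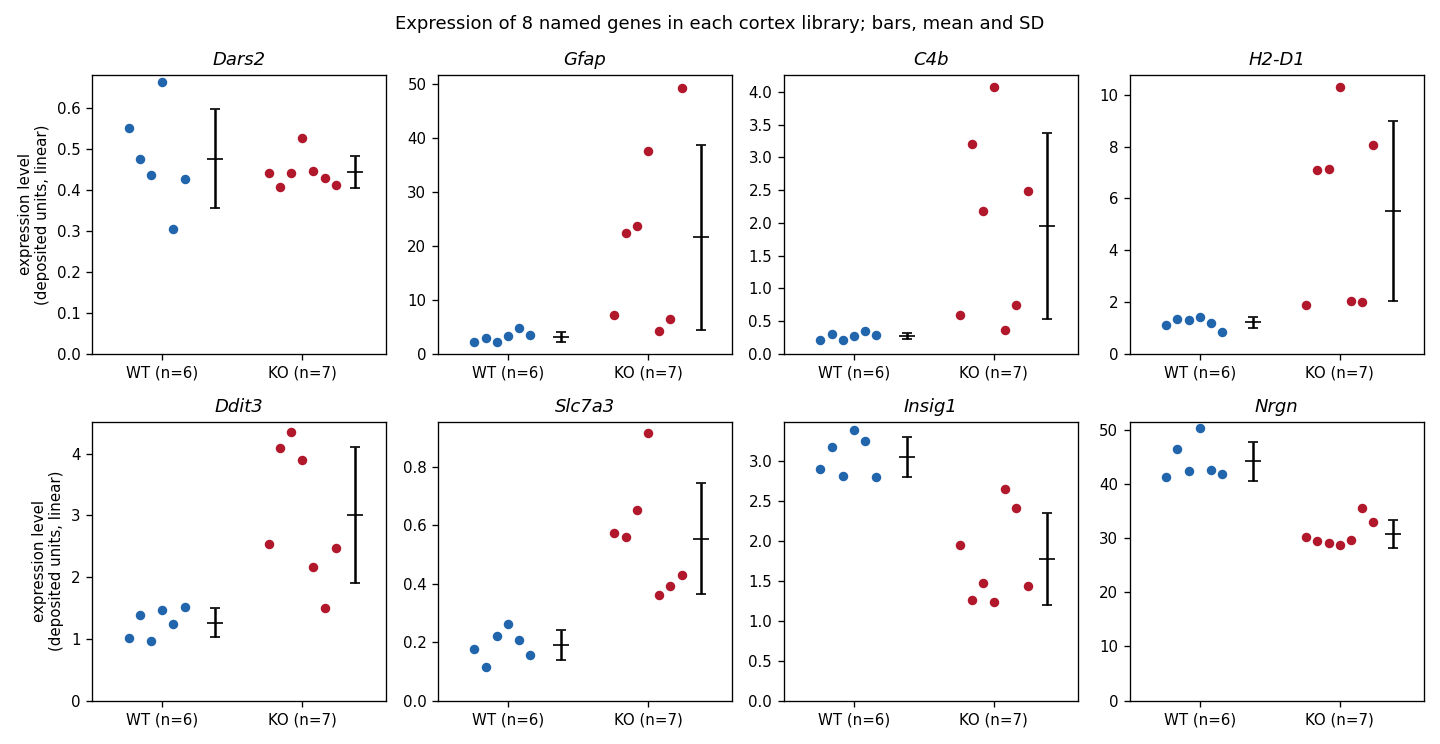
Linear expression level, in the deposited units, of 8 genes in each WT (n = 6, blue) and KO (n = 7, red) library, with the group mean and SD as black bars. Dars2 overlaps between the groups, all 7 KO libraries lie above all WT libraries for C4b, H2-D1 and Slc7a3, and all 7 lie below them for Insig1 and Nrgn.

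Between KO and WT, 427 of the 12597 tested genes changed, 132 higher and 295 lower in KO. The rises were larger than the falls. The median size of the change was 0.73 on the log2 scale for genes higher in KO and 0.44 for genes lower in KO, and of the 51 genes changed at least 2-fold, 44 were higher. The largest rises by the naming rule were those of Cst7, a cysteine protease inhibitor of activated microglia, Oasl2 and Lgals3bp, which are induced by interferon, the complement gene C4b, the astrocyte filament gene Gfap, the lysosomal phagocyte gene Cd68, the MHC class I gene H2-D1, and Ly6a. The largest falls by the same rule were those of the activity-dependent transcription factor gene Egr3, Fam13b, the sterol sensor partner Insig1, the potassium channel subunit gene Kcnv1, Mfge8, Klf10, Mast3 and Nab2. They ran from a log2 change of -0.98 for Egr3 to -0.76 for Nab2. In limma, 2571 genes had an unadjusted p under 0.05, and the median change of all tested genes was -0.01. After quantile normalization 123 genes were higher and 141 lower, and after median centring 153 were higher and 366 lower. With edgeR 154 were higher and 183 lower. Among genes with a mean level of at least 5, 35 were higher and 222 lower, with a median change of -0.0862. The size of the excess of falls thus differed between scalings and was larger among highly expressed genes. Mfge8 lost its call after quantile normalization (adjusted p = 0.054) and with edgeR (adjusted p = 0.719). With no filter 17 of the named genes lost their call, with adjusted p-values from 0.0515 to 0.0728. The count moved by over 1.5 times on leaving out single libraries. It was 168, 147, 138, 682, 869 and 283 without KO replicates 2, 3, 4, 5, 6 and 7, and 164, 246, 92, 168 and 159 without WT replicates 2, 3, 4, 5 and 6. Of the 58 named genes besides Dars2, 17 kept their call without each of the 13 libraries and 41 lost it without at least 1.

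Targets of the integrated stress response, the program that the transcription factor ATF4 drives when translation or mitochondria are disturbed, had a higher mean score in KO. Of 27 tested members 9 rose and none fell, and 14 rose when adjusted over the list alone. Slc7a3, a cationic amino acid transporter (chromosome X, 101079210 to 101086020), rose 2.88-fold from 0.190 ± 0.052 (SD, n = 6) to 0.555 ± 0.191 (SD, n = 7). Ddit3, the stress transcription factor CHOP (chromosome 10, 127290774 to 127296288), rose 2.27-fold, Chac1, which degrades glutathione, rose 2.24-fold, and Sesn2, a stress-induced regulator of growth signalling, rose 2.21-fold. Adjusted p was 0.011 for Slc7a3, 0.0185 for Ddit3, 0.0177 for Chac1 and 0.0130 for Sesn2. All 4 kept their call without each of the libraries, although Slc7a3 had 32 unique reads in KO and 11 in WT. The asparagine synthetase gene Asns and the mitochondrial serine pathway gene Shmt2 also rose, by 0.55 and 1.02 on the log2 scale. The score of the list was above every WT library in 6 of 7 KO libraries, with 0.131 in KO replicate 6 against a highest WT value of 0.156. KO replicates 1 to 7 had stress scores of 0.442, 0.666, 0.711, 0.768, 0.273, 0.131 and 0.486, highest in the 3 libraries with the highest microglia marker scores and lowest in the 2 with the lowest, a relation that was not tested. Camera gave the list an adjusted p of 3.84e-11, and the adjusted p was 0.165 with an estimated correlation.

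The list of synthetases that charge tRNAs in the cytosol, many of which are ATF4 targets, had 23 tested members, including the accessory proteins Aimp1, Aimp2 and Eef1e1. Of these members 4 rose, Sars by 1.38-fold, Tars by 1.38-fold, Gars by 1.30-fold and Eprs by 1.21-fold, and none fell. Adjusted over the list alone, 11 synthetases rose and the accessory protein gene Aimp2 was the 1 member that fell. The call of Sars was kept without each of the 13 libraries but not by edgeR (adjusted p = 0.0957), and the calls of Tars, Gars and Eprs were lost in 11, 5 and 12 of the 13 fits that left out 1 library. Tars and Eprs also lost it with no filter (adjusted p = 0.0659 and 0.0728) and without trend and robust options (0.0518 and 0.0636), with a pseudocount of 1 (0.0529 and 0.0519), Tars after quantile normalization (0.0556) and Eprs after median centring (0.0508) and with a pseudocount of 0.1 (0.0503). Camera gave an adjusted p of 2.69e-08 (adjusted p = 0.183 with an estimated correlation), and the score was higher in 7 of 7 KO libraries than in any WT library. None of the 14 tested mitochondrial synthetases, the family of Dars2, was called, and adjusted over the list alone the count was also 0. Their median log2 change was 0.02 and the camera adjusted p 0.346 (adjusted p = 0.490 with an estimated correlation). Among 20 mitochondrial chaperones and proteases, the import chaperone gene Hspa9 was the 1 member that rose, 1.35-fold in 7 of 7 KO libraries, with its call lost without KO replicate 4 or WT replicate 4, and it was also the 1 member adjusted over the list alone. The list passed camera (adjusted p = 0.0139, and adjusted p = 0.336 with an estimated correlation), but not at a mean level of 5 (adjusted p = 0.060), with fry (adjusted p = 0.0935) or in the exact permutation of its score (adjusted p = 0.158).

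Of the 13 protein genes of the mitochondrial genome mt-Co3 rose 1.52-fold and mt-Cytb 1.45-fold, each in 7 of 7 KO libraries above all WT libraries, and 11 were not called. The call of mt-Cytb was kept without each of the 13 libraries, and that of mt-Co3 was lost in 8 of the 13 fits. Adjusted over the list alone 6 rose. mt-Nd2 had a log2 change of -0.29 without a call. The list passed camera (adjusted p = 6.78e-05, and adjusted p = 0.437 with an estimated correlation), but did not pass fry (adjusted p = 0.0972), and its score did not pass the exact permutation (adjusted p = 0.154). Mitochondrial rRNA took 42.7% ± 3.74 of unique reads in KO (SD, n = 7) and 37.0% ± 2.67 in WT (SD, n = 6), an exact permutation p of 0.0111, although neither mt-Rnr1 (adjusted p = 0.138) nor mt-Rnr2 (adjusted p = 0.335) was called and each was above every WT library in 4 of 7 KO libraries. Of 39 nuclear genes of complexes II to V and cytochrome c, Cox8a fell by 0.41 on the log2 scale and 38 were not called, and 1 fell adjusted over the list alone (camera adjusted p = 0.000362, and adjusted p = 0.527 with an estimated correlation), and their scores did not pass the exact permutation (adjusted p = 0.258), nor did the list pass camera at a mean level of 5 (adjusted p = 0.303) or fry (adjusted p = 0.268). Cox8a lost its call in 5 of the 13 fits that left out 1 library. Of 35 complex I subunits none was called by limma, adjusted over all genes or adjusted over the list alone, with a median log2 change of -0.08 (camera adjusted p = 0.0343, and adjusted p = 0.610 with an estimated correlation). The complex I list lost its camera call without KO replicates 1, 2 or 5 or WT replicates 2, 5 or 6, after quantile normalization (adjusted p = 0.75), with the 18S covariate (adjusted p = 0.121), at a mean level of 1 (adjusted p = 0.245) and with edgeR (adjusted p = 0.136). It also did not pass fry (adjusted p = 0.363) or the exact permutation of scores (adjusted p = 0.432). Its lowest scores were -0.272, -0.266 and -0.192 in KO replicates 5, 1 and 2 and -0.164 and -0.154 in WT replicates 1 and 3. These were the libraries with a Malat1 share of at least 1.49% of unique reads, a relation that was not tested. Mitochondrial ribosomal proteins gave 1 fall, Mrpl20, in 73 members (0 adjusted over the list alone), and factors of mitochondrial DNA maintenance and expression gave none in 20, with camera adjusted p-values of 0.998 and 0.305. The median and mean of the ribosomal list differed in sign, at 0.03 and -0.01. Mrpl20 lost its call in 7 of the 13 fits, with no filter (adjusted p = 0.0534), after quantile normalization (adjusted p = 0.070) and without trend and robust options (adjusted p = 0.0558).

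**Figure D2:**
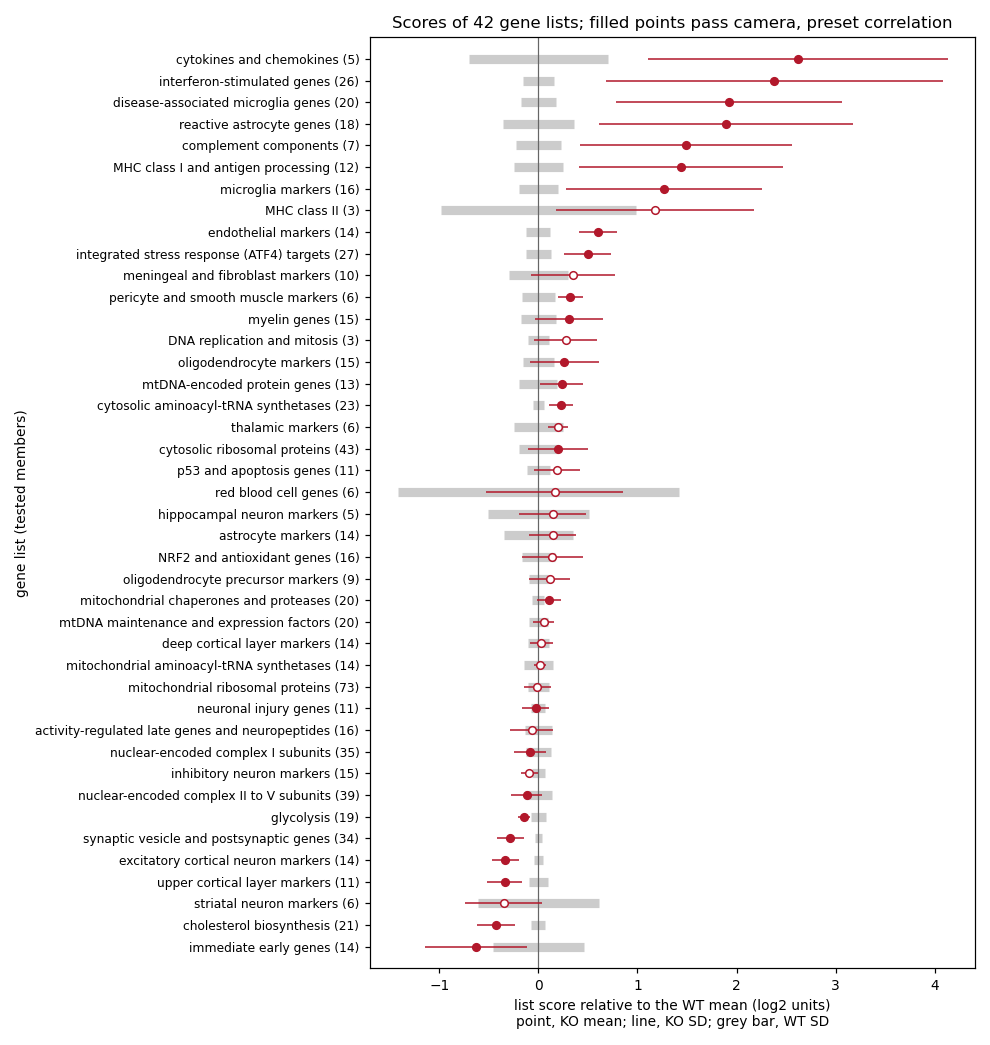
Mean score of each of 42 gene lists in KO relative to the WT mean, on the log2 scale, with the KO SD (n = 7) as a line and the WT SD (n = 6) as a grey bar. Filled points are the 25 lists that passed camera at the preset correlation, 16 up and 9 down, of which none passed with an estimated correlation (smallest adjusted p = 0.0708), and immune lists at the top had KO SDs of about 1 or more.

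Lists of interferon signalling, microglia and reactive astrocyte genes had higher mean scores in KO, and these scores ranged widely among the KO libraries. Of 26 tested interferon-stimulated genes 6 rose (24 adjusted over the list alone), with a median log2 change of 2.23 over the list. The interferon regulator Irf7 rose 12.3-fold, from 0.0503 ± 0.0203 (SD, n = 6) to 0.903 ± 0.797 (SD, n = 7), and Usp18, a feedback inhibitor of the interferon receptor, rose 13.4-fold. The score of the list in KO replicates 1 to 7 was 0.63, 3.35, 3.28, 4.28, 0.27, 0.94 and 3.90, and in WT it lay between -0.19 and 0.22. The KO SD of this score was 10.9 times the WT SD. The test of spread, on absolute deviations from the group median, gave an exact permutation p of 0.0396 that did not pass adjustment over the lists (adjusted p = 0.368). Unique reads of these KO libraries in the same order were 6329894, 6303132, 7014116, 7369914, 5107753, 5303496 and 7262828, so the 3 deepest had high scores and the 2 shallowest had low ones. Irf7 had 4 unique reads in WT and 62 in KO, and the call of Usp18 was lost in 9 of the 13 fits that left out 1 library and by edgeR (adjusted p = 0.0525). With a pseudocount of 1 limma called neither Irf7 (adjusted p = 0.093) nor Usp18 (adjusted p = 0.115), and Usp18 was also not called with a pseudocount of 0.1 (adjusted p = 0.0589). Camera gave an adjusted p of 3.18e-18 and the exact permutation of scores an adjusted p of 0.0276, whereas adjusted p was 0.199 with an estimated correlation. The MHC class I list had 1 rise in 12 members, H2-D1 (chromosome 17, 35262730 to 35267499), at 3.69-fold, and 10 rises adjusted over the list alone (camera adjusted p = 3.44e-08, and adjusted p = 0.202 with an estimated correlation). B2m, the gene of the MHC class I light chain, had a level of 21.01 ± 14.4 (SD, n = 7) in KO and 5.77 ± 0.879 (SD, n = 6) in WT and was not called (limma adjusted p = 0.107). Complement had 1 rise in 7 members, C4b, at 5.32-fold, and 7 adjusted over the list alone (camera adjusted p = 1.25e-06, and adjusted p = 0.199 with an estimated correlation).

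Genes that mark microglia in degenerating tissue gave 3 rises in 20 members, Cst7, Clec7a and Cd68, and 17 adjusted over the list alone (camera adjusted p = 1.16e-12, and adjusted p = 0.202 with an estimated correlation). Cd68 rose 4.59-fold. Cst7 was at the floor in 5 of 6 WT libraries, and its unique reads were 1066 in KO and 4 in WT, a ratio of 236 after scaling to depth that rests on 4 reads of 1 WT library. Clec7a had 40 unique reads in KO and 2 in WT, too few for a firm ratio, and its call was lost in 11 of the 13 fits that left out 1 library and with pseudocounts of 0.1 (adjusted p = 0.0574) and 1 (adjusted p = 0.101). General microglia markers gave 1 rise in 16 members, Cd68, and 14 adjusted over the list alone. Hexb had a level of 8.77 ± 4.79 (SD, n = 7) in KO and 3.22 ± 0.442 (SD, n = 6) in WT (limma adjusted p = 0.0831), and the list passed camera (adjusted p = 1.09e-10, and adjusted p = 0.202 with an estimated correlation). Reactive astrocyte genes gave 3 rises in 18 members, Gfap (chromosome 11, 102887336 to 102900912) at 5.07-fold, H2-D1, and Ggta1 at 3.38-fold (its call was lost in 5 of the 13 fits), and 14 adjusted over the list alone (camera adjusted p = 1.20e-10, and adjusted p = 0.199 with an estimated correlation). Gfap levels in KO were 21.5 ± 17.1 (SD, n = 7) with a range from 4.19 to 49.3, against 3.12 ± 0.939 (SD, n = 6) in WT. Among 14 astrocyte markers Gfap rose and Aldoc fell, and the mean and the median of the list differed in sign, at 0.15 and -0.15 (2 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.164, but 0.0199 without KO replicate 7 and 0.0327 without WT replicate 3). Of 5 cytokines and chemokines none was called, 4 rose adjusted over the list alone, and the list passed camera (adjusted p = 0.00129, and adjusted p = 0.202 with an estimated correlation). The calls of Oasl2, Lgals3bp, C4b, Gfap, Cd68 and H2-D1 were each lost without any of KO replicates 2, 3, 4 and 7 or any WT replicate, and were kept without KO replicates 1, 5 or 6. A pseudocount of 1 ended the calls of these 6 genes (adjusted p = 0.125, 0.0833, 0.0699, 0.0528, 0.0703 and 0.0553 in that order) and of Cst7 (adjusted p = 0.129). With no filter Oasl2, Lgals3bp, Gfap and H2-D1 were not called (adjusted p = 0.0647, 0.0515, 0.062 and 0.0533). Oasl2 also lost its call after quantile normalization (adjusted p = 0.063), with a pseudocount of 0.1 (adjusted p = 0.0724) and without trend and robust options (adjusted p = 0.0605), and Lgals3bp with edgeR (adjusted p = 0.0559). Across the fits that left out 1 library their log2 changes stayed positive, from 2.06 to 2.65 for Gfap and from 1.68 to 2.09 for H2-D1.

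Markers of excitatory neurons and synaptic genes had lower mean scores in KO. Of 14 tested excitatory neuron markers 5 fell and none rose, and 8 fell adjusted over the list alone. Nrgn, a calmodulin-binding protein of dendrites (chromosome 9, 37544492 to 37552904), fell from 44.3 ± 3.57 (SD, n = 6) to 30.8 ± 2.55 (SD, n = 7), a log2 change of -0.52 with an adjusted p of 0.00956, in 7 of 7 KO libraries. Camk2a, a kinase of excitatory synapses, had a log2 change of -0.58, and edgeR on unique reads made no call (adjusted p = 0.71). Camk2a had 164 and 202 unique reads in KO and WT. These leave out reads shared with similar transcripts, which the deposited levels include, so edgeR tested only part of its reads. Cnih3 fell by 0.37 and Baiap2 by 0.32 on the log2 scale, and neither was called by edgeR (adjusted p = 0.123 and 0.162) or after quantile normalization (adjusted p = 0.062 and 0.0564). Their calls were lost in 11 and 3 of the 13 fits that left out 1 library, and that of Cnih3 also with no filter (adjusted p = 0.067) and without trend and robust options (adjusted p = 0.0615). The glutamate transporter gene Slc17a7 had levels of 21.02 ± 1.06 (SD, n = 7) and 22.9 ± 1.14 (SD, n = 6) and was not called (limma adjusted p = 0.239). The list passed camera (adjusted p = 6.45e-08, and adjusted p = 0.0708 with an estimated correlation) and its score lay below all WT libraries in 7 of 7 KO libraries. Genes of synaptic vesicles and postsynaptic sites gave 11 falls in 34 members, among them Snap25, Stx1a and Homer1, and 21 adjusted over the list alone. Snap25, a protein of vesicle fusion, fell by 0.44 on the log2 scale from 87.0 ± 7.16 (SD, n = 6) to 64.7 ± 9.03 (SD, n = 7). Its call was lost after quantile normalization (adjusted p = 0.106) and in 8 of the 13 fits that left out 1 library, as was that of Homer1 in 9. edgeR did not call Stx1a (adjusted p = 0.896), which had only 74 and 80 unique reads in KO and WT, or Homer1 (adjusted p = 0.193). Homer1 also lost its call with no filter (adjusted p = 0.0645), after quantile normalization (adjusted p = 0.101) and without trend and robust options (adjusted p = 0.0667). The synaptic scores of KO replicates 1 to 7 were -0.18, -0.38, -0.40, -0.41, -0.18, -0.07 and -0.36, so the 4 lowest belonged to the 4 libraries with the highest interferon scores, a relation across libraries that was not tested. Camera gave an adjusted p of 6.65e-14 (adjusted p = 0.170 with an estimated correlation).

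Markers of upper cortical layers gave 3 falls in 11 members, Rorb, Lamp5 and Mef2c, and 7 adjusted over the list alone (camera adjusted p = 5.47e-05, and adjusted p = 0.188 with an estimated correlation). Rorb fell by 0.65 and Lamp5 by 0.51 on the log2 scale, and Mef2c had the opposite sign with edgeR on unique reads, at 0.12. Their calls were lost in 10, 8 and 11 of the 13 fits that left out 1 library, and all 3 were lost after quantile normalization (adjusted p = 0.0564, 0.0646 and 0.186) and without trend and robust options, here called plain moderation (adjusted p = 0.0628, 0.0545 and 0.0611). With no filter Rorb and Mef2c were not called (adjusted p = 0.0664 and 0.0544), nor was Lamp5 with edgeR (adjusted p = 0.706). None of 14 deep layer markers was called, 1 rose adjusted over the list alone, and their median and mean differed in sign, at -0.03 and 0.03 (camera adjusted p = 0.746). Among 15 inhibitory neuron markers the GABA transporter gene Slc6a1 was the 1 that fell, by 0.25 on the log2 scale, with its call lost in 10 of the 13 fits that left out 1 library and under no filter, quantile normalization, plain moderation and edgeR (adjusted p = 0.0656, 0.212, 0.0668 and 0.060), and 1 fell adjusted over the list alone (camera adjusted p = 0.248). Gad1 had levels of 6.38 ± 0.759 (SD, n = 7) and 6.70 ± 0.572 (SD, n = 6). Immediate early genes, which follow neuronal firing, gave 1 fall in 14 members, Egr3, at 1.97-fold (its call was lost in 6 of the 13 fits), and 5 adjusted over the list alone. Fos had levels of 1.58 ± 0.891 (SD, n = 7) and 3.05 ± 0.998 (SD, n = 6) without a call (limma adjusted p = 0.114). The list passed camera (adjusted p = 6.78e-05, and adjusted p = 0.369 with an estimated correlation), but did not pass fry (adjusted p = 0.0872), and its score did not pass the exact permutation (adjusted p = 0.118). Late activity-regulated genes gave 3 falls in 16 members, Nrn1, Homer1 and Nptx1 (calls lost in 8, 9 and 1 of the 13 fits), and 2 rises and 6 falls adjusted over the list alone (camera adjusted p = 0.228, but 0.0416 with no filter, 0.0248 with edgeR and 0.0488 without KO replicate 7). Nrn1 lost its call with no filter, after quantile normalization, with plain moderation and with edgeR (adjusted p = 0.0544, 0.0653, 0.0603 and 0.0625). Neuronal injury genes gave 1 fall in 11, Tubb3 (its call was lost in 6 of the 13 fits and after quantile normalization, adjusted p = 0.0785), with 1 rise and 3 falls adjusted over the list alone (camera adjusted p = 0.0324, and adjusted p = 0.226 with an estimated correlation). That list lost its call without KO replicate 6, WT replicate 4 or WT replicate 5 and after quantile normalization (adjusted p = 0.145), at a mean level of 5 (adjusted p = 0.0585) and with the 18S covariate (adjusted p = 0.053). With no filter it was also lost (adjusted p = 0.152) and the list mean turned from -0.03 to 0.295. Its score did not pass the exact permutation (adjusted p = 0.73).

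**Figure D3:**
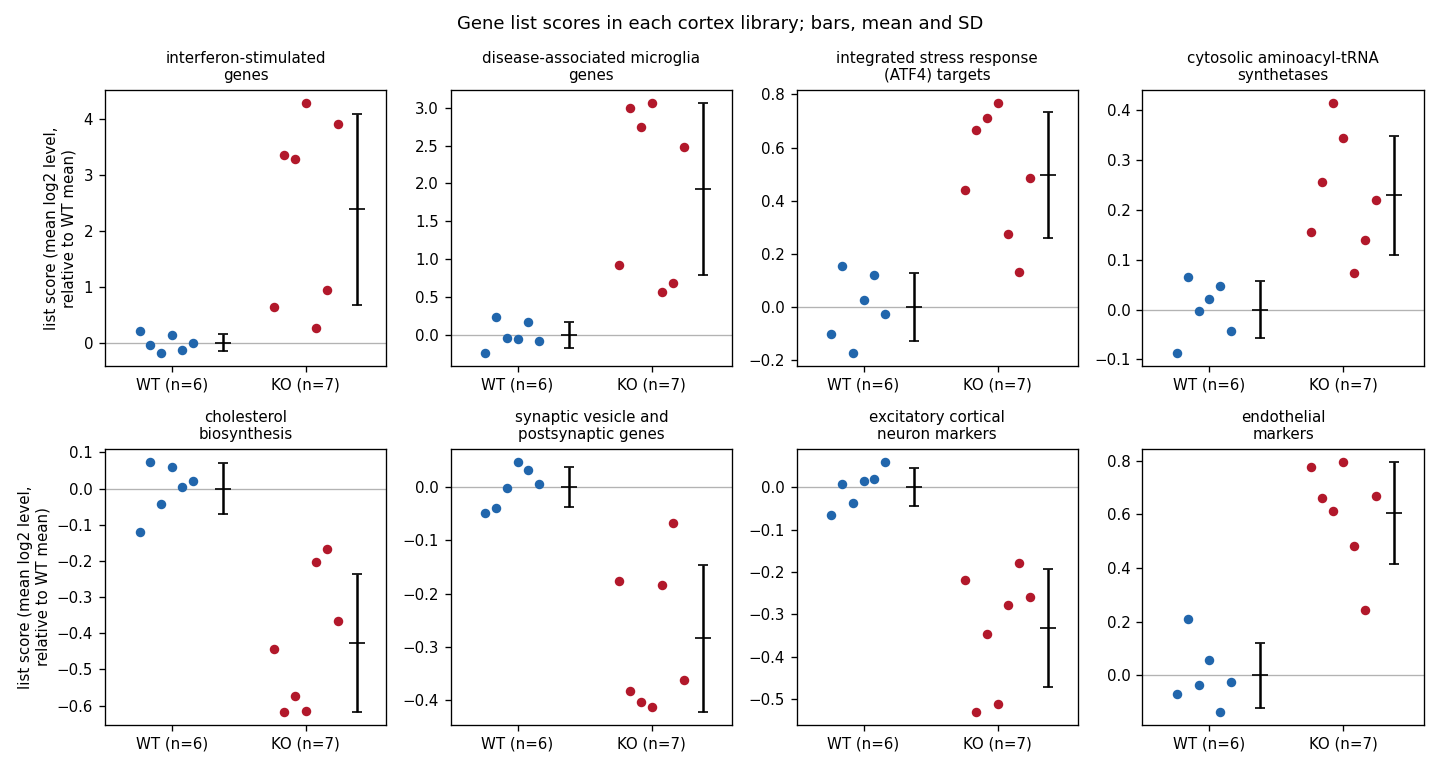
Scores of 8 gene lists, the mean log2 level of the members relative to the WT mean, in each WT (n = 6, blue) and KO (n = 7, red) library, with the group mean and SD as black bars. KO scores of interferon-stimulated genes spread from 0.27 to 4.28, and KO scores of the cholesterol, synaptic and excitatory lists lie below those of all WT libraries.

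Genes of cholesterol synthesis, with its regulators and the receptor for uptake, had a lower mean score in KO. Of 21 members 8 fell and none rose, and 15 fell adjusted over the list alone. Insig1 (chromosome 5, 28071363 to 28078662) fell from 3.06 ± 0.248 (SD, n = 6) to 1.77 ± 0.573 (SD, n = 7), a log2 change of -0.84. The low-density lipoprotein receptor gene Ldlr fell by 0.90, Idi1 by 0.73 and Cyp51 by 0.70 on the log2 scale, and Hmgcr, the rate-limiting enzyme of the pathway, fell by 0.63. The calls of Insig1, Ldlr and Idi1 were lost in 1, 11 and 8 of the 13 fits that left out 1 library, and that of Cyp51 in none. Ldlr also lost it with no filter (adjusted p = 0.0643) and without trend and robust options (adjusted p = 0.0524). The score was below all WT libraries in 7 of 7 KO libraries. In KO replicates 1 to 7 it was -0.445, -0.618, -0.575, -0.615, -0.202, -0.168 and -0.367, with the smallest falls in the 2 libraries of lowest microglia marker score, 5 and 6, and the largest in the 3 of highest, 2 to 4, a relation that was not tested. Camera gave an adjusted p of 1.61e-09, the exact permutation of scores an adjusted p of 0.0128, and adjusted p was 0.165 with an estimated correlation. Glycolysis genes gave 3 falls in 19 members, Aldoc, Eno1 and Pfkp, of 0.43, 0.34 and 0.25 on the log2 scale, and 9 adjusted over the list alone (camera adjusted p = 2.11e-05, and adjusted p = 0.199 with an estimated correlation). edgeR called none of these 3 (adjusted p = 0.491, 0.851 and 0.87), although Aldoc had only 42 and 72 unique reads in KO and WT. Quantile normalization ended the calls of Eno1 and Pfkp (adjusted p = 0.0697 and 0.153). The calls of Aldoc, Eno1 and Pfkp were also lost in 2, 9 and 8 of the 13 fits, those of Eno1 and Pfkp without trend and robust options (adjusted p = 0.0605 and 0.0529), and that of Eno1 with no filter (adjusted p = 0.054).

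The mean score of endothelial markers was higher in 7 of 7 KO libraries than in any WT library. Of 14 members 4 rose, Ly6a, Vwf, Pecam1 and Esam, and 11 rose adjusted over the list alone. Pecam1, an adhesion molecule of vessel walls, rose 1.67-fold and Ly6a, which interferon also induces, rose 2.82-fold, while Vwf had only 20 unique reads in KO and 2 in WT. The call of Pecam1 was kept without each of the 13 libraries, those of Ly6a, Vwf and Esam were lost in 1, 7 and 10 of the fits, and edgeR called neither Ly6a (adjusted p = 0.129) nor Esam (adjusted p = 0.0567). Vwf and Esam lost the call after quantile normalization (adjusted p = 0.0529 and 0.0617) and Esam with no filter (adjusted p = 0.0573). Cldn5 had levels of 1.11 ± 0.269 (SD, n = 7) and 0.921 ± 0.140 (SD, n = 6) without a call (limma adjusted p = 0.392). Camera gave an adjusted p of 8.96e-09 (adjusted p = 0.0708 with an estimated correlation). Pericyte markers gave no call in 6 members and 1 rise adjusted over the list alone, and passed camera (adjusted p = 0.0246, and adjusted p = 0.183 with an estimated correlation) except without KO replicate 5. Myelin genes and oligodendrocyte markers, which share most members, each gave 1 rise in 15, Ugt8a, with 4 rises and 1 fall and with 3 rises adjusted over the list alone (camera adjusted p = 0.000160 and 0.00266, and adjusted p = 0.437 and 0.487 with an estimated correlation). The call of Ugt8a was lost in 10 of the 13 limma fits that left out 1 library. It was also lost with edgeR (adjusted p = 0.847), with no filter (adjusted p = 0.0544) and with plain moderation (adjusted p = 0.056). Both lists failed fry (adjusted p = 0.164 and 0.243) and the exact permutation of scores (adjusted p = 0.158 and 0.208). None of 43 cytosolic ribosomal protein genes was called by limma, adjusted over all genes or adjusted over the list alone, yet all 43 had positive values with a median of 0.19 on the log2 scale (camera adjusted p = 4.89e-07, and adjusted p = 0.490 with an estimated correlation). The exact permutation of their scores gave an adjusted p of 0.295 and fry an adjusted p of 0.284. The 4 lowest scores came from both groups, -0.226 and -0.263 in WT replicates 1 and 3 and -0.105 and -0.18 in KO replicates 1 and 5, which were among the 5 libraries with a Malat1 share of at least 1.49% of unique reads, a relation that was not tested.

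The remaining lists did not pass camera under the main settings. Among 11 p53 and apoptosis genes Ccng1 rose 1.44-fold and 10 were not called (2 rose adjusted over the list alone, camera adjusted p = 0.116). Antioxidant genes (16 members), MHC class II (3), DNA replication (3), oligodendrocyte precursor (9), meningeal (10), hippocampal (5), thalamic (6) and striatal (6) markers and red blood cell genes (6) had no called member. Their camera adjusted p-values were 0.233, 0.184, 0.233, 0.323, 0.0808, 0.647, 0.342, 0.118 and 0.923 in that order. The red blood cell list had a positive mean, 0.16, and a negative test direction. Some of these lists passed under other settings. With no filter p53 genes, MHC class II, replication genes and meningeal markers did (adjusted p = 0.0218, 0.00517, 0.007 and 0.0478). With edgeR the same 4 lists (adjusted p = 0.00451, 0.0101, 0.0327 and 0.0252) and striatal markers (adjusted p = 0.0421) did. Meningeal markers passed without KO replicates 1, 6 or 7 or WT replicate 5 (adjusted p = 0.0352, 0.0297, 0.0349 and 0.0386), striatal markers without KO replicate 7 or WT replicate 3 (adjusted p = 0.0263 and 0.0406), and p53 genes without WT replicate 6 (adjusted p = 0.0363). Adjusted over the list alone, 2 striatal markers fell and 1 replication gene and 1 thalamic marker rose.

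In the authors' deposited table, 515 genes had a posterior probability above 0.5, 228 with a positive and 287 with a negative effect, and 158 of them were among the genes tested here. Of the 427 limma calls, 55 were shared, all 55 with the same sign, where 5.36 are expected for independent lists of these sizes. Both analyses used the same libraries. In the authors' deposited table the stress genes Sesn2, Slc7a3 and Chac1 had posteriors of 0.854, 0.766 and 0.643, and Ddit3 had 0.433. The cholesterol genes Idi1 and Cyp51 had 0.888 and 0.64, and Ldlr and Insig1 had 0.358 and 0.106. Every rise named from the interferon, MHC class I, complement, microglia and reactive astrocyte lists stayed below 0.5. These posteriors ran from 0.107 for Oasl2 to 0.498 for Cst7, with Gfap at 0.109. Among excitatory neuron markers Nrgn had 0.704, and Camk2a, Cnih3 and Baiap2 had 0.229, 0.27 and 0.203. Dars2 had a posterior of 0.00904 there.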

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

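The tests of labels, depth, 18S rRNA, ages, scaling, neuron shares and Dars2 transcript were chosen after the results were seen, and the splits of the libraries were not.

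The 7 KO libraries ranged widely in immune and reactive glial genes, with interferon scores from 0.27 to 4.28 and microglia marker scores from 0.13 to 2.26, while WT scores lay between -0.19 and 0.22 and between -0.27 and 0.23, although no list passed the adjusted test of spread (adjusted p = 0.368 for interferon genes). Wrong genotype labels on some KO libraries remain possible: over genes in no immune or glial list and called without the library judged, 5 of 7 KO libraries lay nearer the KO mean, while KO replicates 5 and 6 lay nearer the WT mean. On a scale from 0 at the WT mean to 1 at the KO mean those 2 stood at 0.464 and 0.321 and the highest of the 6 WT libraries at 0.212, so a weaker response in animals with the right label would give the same values. Their excitatory neuron scores (-0.278 and -0.179) and cholesterol scores (-0.202 and -0.168) lay below every WT library (lowest -0.0648 and -0.119). Both are lists in which all 7 KO libraries lay below every WT library. They were picked with the labels of KO replicates 5 and 6 in use, so these scores cannot weigh against a wrong label. Other scores of these 2 libraries lay within the WT range, among them microglia markers (0.128 and 0.191, highest WT 0.228) and the stress score of KO replicate 6 (0.131, highest WT 0.156). Differences in 18S rRNA carry-over are argued against by the WT libraries, which without their most distant library spanned 71.9% of the KO range of 18S share, but with it 10% of that of the interferon score. Depth alone did not give a high interferon score: WT replicates 1, 2, 4, 5 and 6 had more unique reads than KO replicate 2 (6303132), but scores of at most 0.215 against its 3.35. At a like depth, WT replicate 5 (7000204) scored -0.132 and KO replicate 3 (7014116) 3.28. Depth as a source of the spread within KO cannot be told apart from other causes: without WT replicate 3 the WT libraries spanned 18.6% of the KO range of depth, and with it 62.4%. The 3 deepest KO libraries had interferon scores of 3.28, 4.28 and 3.90 and the 2 shallowest 0.27 and 0.94, although KO replicates 1 and 2, of like depth, had 0.63 and 3.35. Sums of linear levels were lowest in KO replicates 1, 5 and 6 (648286, 576350 and 746734), which also had the lowest interferon scores. Their Malat1 shares were 1.63%, 1.49% and 1.21% of unique reads, but KO replicate 2 had 1.61%. Among WT libraries the sums ran from 596384 to 1408089 and the Malat1 shares from 0.796% to 1.72%, with interferon scores of at most 0.215. These relations were not tested. Animals of different ages within the KO group cannot be told apart from other causes either, since the labels give 1 age for all 7 and the series text gives another, so a difference between animals in how far the response had gone may remain as a hypothesis.

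The mean score of excitatory neuron markers was lower in 7 of 7 KO libraries than in any WT library, although 9 of the 14 markers were not called and the list did not pass with an estimated correlation (adjusted p = 0.0708). A scaling difference between the groups is argued against by the mean of the list, which was -0.33 on the log2 scale and still -0.31 after quantile normalization (-0.315) and -0.35 after median centring. A lower share of all neurons as the only cause is argued against by the excitatory minus inhibitory score, which differed by -0.242 (exact permutation p = 0.00233, lower in 7 of 7 KO libraries). This score cannot exclude a smaller loss of all neurons beside another cause. Inhibitory markers had a mean log2 change of -0.09, with scores below all WT libraries in 4 of 7 KO libraries (exact permutation p = 0.0624 before adjustment). Even loss of excitatory neurons across layers as the only cause is argued against by the upper minus deep layer score, which differed by -0.371 (exact permutation p = 0.00641, lower in 6 of 7 KO libraries). KO replicate 5, with the lowest interferon score of the KO libraries, had their lowest upper layer score (-0.527) and highest deep layer score (0.26). Loss of upper layer neurons, a smaller loss of all neurons and lower expression in surviving neurons remain open and may act together, since bulk RNA gives no cell counts.

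No lower level of Dars2 RNA was detected in KO cortex. Transcript counted outside the deleted exons or in cells without Cre may hide a loss in the deleted neurons, and the interval allows a fall of up to 24.2%. This cannot be told apart from no loss, because only gene-level values were analysed here.

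Counts of changed genes as large as the real ones did not arise in the other splits drawn. Only 100 of the 1716 possible splits were used. Splits that mix KO and WT libraries can also widen the spread within groups, which lowers their counts. The splits cover random grouping only, not another difference between the groups that follows genotype. Of 100 splits of the 13 libraries into 7 and 6, the real one included, 1 gave as many changed genes (427, highest other 5), 1 as many higher (132, highest other 1), 1 as many lower (295, highest other 4) and 1 as many changed at least 2-fold (51, highest other 2). For lists passing camera 3 splits gave as many, and the highest other count, 28, was above the real count of 25. Most of the drawn splits also passed lists, and 1 that moved 3 KO libraries passed 23. The correlation estimated for interferon genes was 0.815, against the preset 0.01. Passing camera at the preset correlation, however small its p, is therefore weak evidence by itself that a list follows genotype.

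In 206 groups of libraries tested for 1 library far from the rest, 11 stood out, where chance gives about 1 in 20, or 10.3. The gap to the nearest library, as a share of the group's range, is given for each. KO replicate 4 was highest for Dars2 (0.647, a level of 0.528 against 0.447). WT replicate 2 was highest for Cst7 (0.956), as the 1 WT library above the floor. WT replicate 6 was highest for Fam13b (0.752) and Nab2 (0.625), WT replicate 5 for Mast3 (0.706, a level of 4.61 against 3.31) and WT replicate 4 for Sesn2 (0.884, a level of 0.239 against 0.157). Among list scores, WT replicate 3 was lowest for meningeal markers (0.638) and astrocyte markers (0.631), WT replicate 6 was highest for p53 and apoptosis genes (0.789), and KO replicate 7 was highest for astrocyte markers (0.740). WT replicate 3 also had the lowest depth of its group (0.702).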

How the results depend on the processing

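The filter at a mean level of 1, the 18S covariate, edgeR on unique reads and the permutation of list scores were chosen after seeing the data. The main counts were 427 genes changed, 132 higher, 295 lower, 51 changed at least 2-fold, 25 lists and 55 calls shared with the authors. Counts within 1.5 times of these are not repeated, and unless stated the cause was not tested. With no filter 266 genes changed and 160 were lower, 17 of the 58 named genes lost their call, 1 list lost it and 5 lists gained it. At a mean level of 5, with 1176 genes tested, 257 changed, 35 higher, 10 at least 2-fold, 21 shared and 10 lists, and complex I subunits reversed in the list test with a mean of -0.0702 (adjusted p = 0.806). Pseudocounts of 0.1 and 1 left 32 and 0 genes changed at least 2-fold, while 404 and 377 genes changed, and 4 and 12 named genes lost their call, at a pseudocount of 1 mainly immune and glial genes. Pseudocounts shrink folds of low genes, but lost calls also lowered the counts at 2-fold. At a pseudocount of 1, Gfap and H2-D1 still had log2 changes of 2.05 and 1.35 without a call (limma adjusted p = 0.0528 and 0.0553). At a mean level of 1, the filter first planned, 6232 genes were tested and 19 changed at least 2-fold. Of the 58 named genes 41 were tested under it, and all 41 kept their call. The rest had mean levels under 1 and were not tested, among them Slc7a3, Chac1, Sesn2, Irf7, Usp18 and Clec7a, nor was Dars2. Quantile normalization gave 264 changed and 141 lower, and 18 named genes and 2 lists lost their call. Without trend and robust options 280 changed and 174 were lower, and 15 named genes lost their call. Sample quality weights gave 769, 245 higher, 524 lower and 107 at least 2-fold. With the 18S covariate 653 changed, 262 higher and 98 at least 2-fold. edgeR gave 183 lower and 96 at least 2-fold, and Dars2 at 0.264 and Mef2c at 0.117 with the opposite sign (adjusted p = 0.85 and 0.861). For 10 of the 58 named genes edgeR had no result, and of the other 48 it ended the calls of 18 more. edgeR saw only unique reads, which were few for some of these genes, so its lack of a call there is weak evidence. It also ended the call of 1 list, and 6 lists gained a call. Of its 337 calls, 175 were shared with limma, all with the same sign. The exact Wilcoxon test called 0 changed, 0 higher, 0 lower, 0 at least 2-fold and 0 shared. It had 2011 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0532. Its smallest possible p, 0.117%, is reached only where the KO and WT ranges do not overlap. The 276 such genes among the 12597 tested were too few to bring that p under 0.05 after adjustment. With so few libraries the rank test therefore cannot decide whether the limma calls hold. With an estimated correlation 0 lists passed. The exact permutation of scores was passed by 16 lists, and directional fry by 17, which ended the call of 8 of the 25 lists and added none.

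Leaving out 1 library at a time gave 92 to 869 genes changed, 37 to 322 higher, 55 to 547 lower, 15 to 151 at least 2-fold, 23 to 29 lists, 18 to 76 shared calls and a Dars2 change from -0.188 to 0.0354, the last without WT replicate 4. Of 58 other named genes, 17 kept their call without each of the 13 libraries, among them Slc7a3, Ddit3, Nrgn, Cyp51, Irf7 and Pecam1, and 41 lost it without at least 1. The authors' estimates kept the direction of all 58 and passed a posterior of 0.5 for 15.

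The replicate numbers do not pair the libraries. Correlations of same-numbered deviations ran from -0.159 to 0.0438, and 0 of 6 KO libraries correlated best with their own number. With the number as a replicate block limma called 0 changed, 0 higher, 0 lower, 0 at least 2-fold and 0 shared, 3 lists gained a call, and limma had 2172 genes at an unadjusted p under 0.05.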

Other observations

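The genes in this paragraph and the next were chosen after their values were seen. The smallest adjusted p of the comparison, 0.00631, belonged to Cyb5r1, a cytochrome b5 reductase, at levels from 0.436 to 0.736 in WT (n = 6) and from 0.957 to 2.12 in KO (n = 7), a log2 change of 1.46 in limma. Kctd1 and Kif5a shared that adjusted p and fell by 0.66 and 0.63 on the log2 scale. Kif5a, a neuronal kinesin of axonal transport, went from 34.95 ± 2.89 (SD, n = 6) to 22.6 ± 2.38 (SD, n = 7), with 152583 and 102834 unique reads behind the groups. Camk2n1, an inhibitor of the CaMKII kinase, fell by 0.68, Phyhip by 0.475 and the microtubule gene Mapt by 0.41 on the log2 scale, each below all WT libraries in 7 of 7 KO libraries.

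Other called genes were the circadian repressor gene Per2 with a log2 change of -1.04 (limma adjusted p = 0.0339), the desaturase gene Scd1 with -0.71 (limma adjusted p = 0.0366), and Apln, the gene of a vascular peptide, with -0.91 (limma adjusted p = 0.0273). The glial glutamate transporter gene Slc1a2 had levels of 25.1 ± 3.56 in KO (SD, n = 7) and 31.1 ± 1.59 in WT (SD, n = 6), lower in 7 of 7 KO libraries than in any WT library, and was not called (limma adjusted p = 0.0636), while Aqp4, another astrocyte gene, had 2.31 ± 1.20 (SD, n = 7) and 1.504 ± 0.334 (SD, n = 6).

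Among the 12597 tested genes, 276 had KO and WT ranges that did not overlap, where chance gives 0.117%, or 14.7 genes. Of these 214 were among the called genes, 69 higher and 145 lower in KO.

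The labels name a poly(A) kit, yet RNAs without a poly(A) tail were abundant. The RNAs of the 7SL and 7SK particles took between 4.88% and 8.30% of unique reads and the 18S rRNA between 0.112% and 2.66%.

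The group means in the authors' deposited table did not match the values per library. The KO mean was listed as -1.6 with an SD of 0 for 63.9% of genes, and 3.41% of KO means and 3.60% of WT means lay within 0.1 of the mean over libraries. The authors' effects did follow the log2 changes computed here, with a Pearson r of 0.881 across genes, which are not independent replicates.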
